A study of Mus musculus with 6 samples.

How the data were processed

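Total RNA from 6 mouse cell samples, 1 sample per group, was hybridised to Affymetrix Murine Genome 430 2.0 arrays after 1 round of amplification, per the labels' protocols. The values were processed by the authors with GCOS 1.3, per the submitters' processing notes. The deposited values are intensities on a linear scale, and on every array the mean signal left after trimming 2% of the probe sets at each end was 150, so each array had been scaled to 1 level. The signal algorithm and its settings are not stated. A deposited workbook held the same GCOS values, with 0 differing values, and beside them a second summary of the same 6 arrays, also linear intensities, whose method is not stated by the authors. The GCOS signal was the main value, and the second summary was an alternative chosen after seeing the data.

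Of the 45101 probe sets, 64 were controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none there. Symbols were compared with a mouse gene table through the Entrez identifier, which held 34741 of the named probe sets and changed 0 symbols. Each of 18193 genes took 1 probe set, chosen first by the specificity that the probe set suffix denotes and then by the highest mean signal. The plan called for Present calls and for a floor set from Absent signals, and the tables hold no calls. The fallback written with the plan was used: signals below the 40th percentile of all signals, 20.4, were set to that floor, and a signal above it counted as present. The same percentile gave a floor of 11.3 for the second summary. A gene below that floor on every array compared could not show a difference there. With this floor 14706 genes were above it on at least 1 array and 10954 on all 6. Values were then taken to log2, and a fold in which 1 array lay at the floor is a lower bound.

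With 1 array per group, comparisons of single arrays have no replicate check, carry no p-value and name genes by size alone. A gene counted as different when the ratio was at least 2-fold and the brighter array was above the floor. A difference of changes between the cell lines also needed a change of at least 2-fold in the R388A/Y527F line in the same direction. The genes named for each comparison were the 8 with the largest rise and the 8 with the largest fall whose other probe sets, where above the floor, had the same sign, with clone names left out. Up to 4 members of each gene list, taken by size of change, and the 8 genes with the largest differences in each direction of each model were also eligible, and Src, Yes1 and Fyn were always named. Genes that passed the 2-fold rule in both summaries were listed as well, a reading chosen after the values were seen.

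Models over all 6 arrays were fitted with limma 3.58.1 in R 4.3.3, with a trend in the variance prior and Benjamini-Hochberg adjustment at 0.05, on 13742 genes above the floor on at least 2 arrays. A model with line and time gave the difference between the lines and the changes at 1 h and 12 h common to both lines, and a model with line, treatment and their interaction gave the difference of treated minus untreated change between lines. Each model left 2 residual degrees of freedom. In the model with line and time, the 3 times stand in for replicates of a line and the 2 lines for replicates of a time. In the interaction model the 1 h and 12 h arrays of a line count as 2 treated samples, and their difference is the error. In simulated data with 200 genes changed by 1 on the log2 scale, the fit recovered 91% for the line difference, 74.5% for the common change at 1 h, 62% for that at 12 h and 39% for the interaction. With a change of 0.5, it recovered 39.5%, 20%, 22% and 2%. Every simulation drew normal noise with the residual spread of the line and time model, with no floor and no other change. The recovery for the interaction therefore leaves out real differences between 1 h and 12 h, which are part of the error in that fit. Beside 182, 149, 124 and 78 recovered genes, the fit called 20, 11, 3 and 6 unchanged ones with a change of 1. With a change of 0.5, it called 10, 2, 5 and 1 unchanged genes beside 79, 40, 44 and 4 recovered. For the line difference and the interaction the false share was above the 0.05 aimed at with both sizes of change. It was also above 0.05 for the common change at 1 h with a change of 1, and for that at 12 h with 0.5.

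The 30 gene lists, covering signalling targets, stress and metabolic pathways, the cell cycle and markers of other cell types, were fixed before the data were examined. A list's median log2 change was placed among the medians of 10000 random lists matched on mean signal, as a description of these arrays, and a list at or below the 2.5th percentile or at or above the 97.5th was said to stand apart. Counts of list members in the limma fits are given over all genes and adjusted over the list alone, the latter without correction across lists. The size rule and the list percentiles were tested on simulated arrays with known changes in bright genes and the same independent noise for every gene. That check does not cover the noise of low signals or genes that vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and matplotlib 3.10.9 drew the plots.

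Arrays give no counts, so the number of arrays limits the precision. Between pairs of probe sets of 1 gene, the spread of a log2 fold of 1 probe set was 0.27 for the GCOS signal and 0.20 for the second summary in the R388A/Y527F line at 1 h. Across these pairs, the 2 folds of a gene in the GCOS signal correlated at 1 h with r = 0.104 in R388A/Y527F and 0.013 in D386N/Y527F. At 12 h r was 0.205 and 0.265, and between the lines at 0 h 0.545. Unchanged pairs of arrays simulated with the residual spread gave a median of 86 genes with a 2-fold difference by chance in the GCOS signal, with a range of 62 to 113, and a median of 1.5 in the second summary, with a range of 0 to 5. The simulated noise was normal, with each gene's variance drawn toward the fitted trend, so these counts are no upper bound on chance. The alternatives were quantile normalization, scaling to the median of probe sets above the floor on all arrays, a pseudocount in place of the floor, the mean of all probe sets of a gene, no filter on calls, no trend, no time term and each time left out. The second summary, a floor at the 60th percentile (55.0) and the 1 h array in place of the 0 h array for lists at 12 h were added after seeing the data. The alignment columns of the workbook name no genome build, and no coordinates are given.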

Results

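Gene expression was measured in SYF cells, mouse embryonic fibroblasts that lack the tyrosine kinases Src, Yes and Fyn. The cells stably carried 1 of 2 Src mutants. Both mutants hold Y527F, a change that removes the inhibitory tyrosine of the Src tail. R388A replaces a catalytic arginine and gives a kinase whose activity imidazole can restore. D386N replaces the catalytic aspartate, and imidazole does not restore it. That line was the control for imidazole and time without a restored kinase, in a separate population of cells. After a night without serum, cells received 5 mM imidazole for 1 h or 12 h or were left at 0 h. Each of the 6 combinations was measured on 1 array, so no group has a replicate. The number of genes above the floor lay between 12457 and 12944 per array. The ratio of 3' to 5' signal lay between 0.76 and 0.82 for Gapdh and between 1.11 and 1.18 for actin. No 12 h sample without imidazole was among the 6.

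The genes missing from SYF cells were read first. The probe set for Src gave signals of 66.9, 19.1 and 42.2 at 0, 1 and 12 h in the R388A/Y527F line and of 58.4, 72.7 and 67.9 in the D386N/Y527F line. A second Src probe set gave 37.8, 30.9 and 22.2 in R388A/Y527F and 36.0, 107.3 and 81.1 in D386N/Y527F, so the 2 did not move together. The probe sets used for Yes1 and Fyn gave signals from 180.6 to 219.4 and from 185.3 to 238.4 on the 6 arrays, while 3 other Yes1 probe sets gave 10.5 to 67.0 and another Fyn probe set 82.3 to 110.3. Whether these probes lie within the deleted parts, or read the introduced Src, is not known from the tables, so these values do not check the labels.

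The comparison of the lines at 0 h asks how they differed before imidazole. The line with R388A/Y527F had much higher levels of genes that the ERK pathway induces. All 18 measured members of the ERK feedback and target list had higher signals in R388A/Y527F than in D386N/Y527F, 12 of them at least 2-fold. The list's median log2 difference was 1.29 (1.38 in the second summary), above every one of 10000 random lists. Dusp6, a phosphatase of ERK, differed by 4.70 on the log2 scale, with signals of 586.0 and 22.6. The ETS factors Etv4 and Etv5 differed by 3.91 and 3.39, and Ccnd1, which encodes cyclin D1, by 3.05. Among immediate early genes, Jun stood at 2.38, Fosl1 at 1.69 and Arc at -1.57, and that list stood at the 98.6th percentile with a median of 0.19 (95.3 in the second summary).

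Several other lists lay on the low side in R388A/Y527F at 0 h. All 14 NRF2 targets were lower, with a median of -0.25 at the 1.17th percentile, among them the heme oxygenase gene Hmox1 at -0.89 and Gclm, of glutathione synthesis, at -0.77. Heat shock genes had a median of -0.35 at the 0.09th percentile, led by the small heat shock protein gene Cryab at -1.77. Sterol synthesis genes had a median of -0.22 at the 1.3rd percentile, with Mvk at -0.56 and Hmgcs1 at -0.54. G2/M genes had a median of -0.20 at the 1.54th percentile, with the cyclin gene Ccnb2 at -0.56. These 4 lists also stood apart, on the same side, in the second summary. Muscle markers had a median of -0.84 and adipocyte markers -0.63 over 3 measured genes each, at the 0.50th and 1.07th percentile. These medians are single genes against the floor, Actc1 and Pparg, with signals of 36.4 and 31.5 in D386N/Y527F. In the second summary adipocyte markers stood at the 2.57th percentile, not apart, and too few muscle markers were above the floor for a median. Neural and glial markers had a median of 0.42 (percentile 94.6), haematopoietic markers -0.02 (32.2) and epithelial markers -0.01 (36.9). Circadian clock genes stood at the 98.7th percentile with 0.38 and at the 50.1st in the second summary. Sterol synthesis, circadian and adipocyte lists no longer stood apart with the mean of all probe sets, immediate early, G2/M and muscle lists under quantile normalization, muscle markers with a pseudocount, and immediate early and circadian lists with a higher floor, at the 60th percentile.

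By the 2-fold rule 446 genes were higher and 280 lower in R388A/Y527F at 0 h, and the second summary gave 248 and 290. Both summaries called 187 genes higher and 150 lower. The named genes on the higher side were Gpr149 (an orphan receptor), Crabp1 (a retinoic acid binding protein), Dusp6, Itga6 (the integrin alpha 6 subunit, a laminin receptor chain), Tenm4, Cavin2 (a caveolar coat protein), Etv4 and Khdrbs3. Their log2 differences lay between 3.63 and 5.00. On the lower side were Npr3 (the natriuretic peptide clearance receptor), Lgals3 (galectin 3), Sned1, Rspo2 (a Wnt agonist), Lbp, Serpinb1a, C1qtnf1 and Radil, between -4.62 and -2.48. All 16 were 2-fold different in the same direction in the second summary, and 10 of them had an array at the floor. Under quantile normalization 51.9% of the called genes were higher in R388A/Y527F, against 61.4% in the GCOS signal as deposited. In the second summary more genes were lower at all 3 times, with 270 higher and 295 lower at 1 h and 270 and 296 at 12 h. In the GCOS signal more were lower only at the later times, with 371 higher and 440 lower at 1 h and 361 and 473 at 12 h. Of the genes higher or lower at 0 h, 33.9% and 35.7% were so at all 3 times (69.8% and 52.1% in the second summary).

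The difference between the lines over all 3 times, the 0 h arrays included, included most of the ERK targets. In the limma fit, the named genes higher in R388A/Y527F were Crabp1 (log2 difference 5.28), Gpr149 (4.95), Dusp6 (4.38, SE 0.17, adjusted p = 2.39e-06), Cavin2 (4.20), Itga6 (3.95), the chromatin protein gene Hmga2 (3.65), Khdrbs3 (3.61) and Tenm4 (3.61). Those lower were Lgals3 (-4.45), Npr3 (-4.01, SE 0.20, adjusted p = 1.11e-05), Sned1 (-2.97), Rspo2 (-2.94), Lbp (-2.70), the interferon-induced Oas1a (-2.53), Lmcd1 (-2.50) and the ceruloplasmin gene Cp (-2.47). Lgals3 and Lbp lay at the floor on all R388A/Y527F arrays and Gpr149 and Khdrbs3 on all D386N/Y527F arrays, so the sizes, errors and order of these genes depend on the floor. In the second summary Gpr149 (6.53) stood above Crabp1 (5.99). Of the 18 ERK list genes, 16 were higher in the limma fit over all genes and 17 when adjusted over the list alone. Ccnd1 differed by 3.01 (SE 0.08), Etv4 by 3.60, Etv5 by 2.99, Dusp4 by 2.25 and Fosl1 by 1.67, while Epha4 stood at -0.22 (adjusted p = 0.66, limma). Among 37 immediate early genes, 10 were higher and 3 lower over all genes, and 12 and 4 adjusted over the list alone. Jun (1.91), Atf3 (1.52) and Myc (1.21) were higher and the matricellular gene Ccn1 (-0.64) lower.

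Interferon-stimulated genes went both ways between the lines, with 3 of 20 higher and 7 lower in limma over all genes, and 4 and 7 adjusted over the list alone. The immunoproteasome gene Psmb9 (-1.82), Usp18 (-1.33) and the peptide transporter gene Tap1 (-1.21) were lower, and Cxcl10 (1.07) and Ifit1 (1.03) higher. Of 14 NRF2 targets 0 were higher and 6 lower over all genes, and also 6 lower adjusted over the list alone, among them Gstm1 (-0.94) and Gsr (-0.80). Of 13 heat shock genes 2 were higher (Hspd1 and Hspe1) and 4 lower over all genes, and 2 and 6 adjusted over the list alone. Matrix and protease genes were split, with Dcn (1.99), Col6a3 (1.52) and Cd44 (0.85) higher and Lox (-1.26), Thbs1 (-1.08) and Mmp14 (-0.72) lower. Of 23 fibroblast matrix genes, 5 were higher and 5 lower over all genes, and 5 and 7 adjusted over the list alone. Of 19 sterol synthesis genes 2 were higher and 6 lower over all genes (2 and 7 adjusted over the list alone), of 22 G2/M genes 0 and 3 (0 and 3) and of 14 circadian clock genes 1 and 2 (1 and 2). In limma on the second summary, over all genes, 16 of 16 ERK targets were higher, and the numbers higher and lower were 6 and 6 of 19 interferon-stimulated genes, 10 and 6 of 34 immediate early genes, 0 and 7 of 14 NRF2 targets, 2 and 7 of 13 heat shock genes, 2 and 10 of 19 sterol synthesis genes, 1 and 9 of 22 G2/M genes and 5 and 8 of 21 matrix genes.

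In total 2881 of 13742 genes differed between the lines in limma, 1351 higher and 1530 lower in R388A/Y527F. Leaving out the 0 h, 1 h or 12 h arrays gave 1708, 642 and 500, the fit without a trend gave 1099 and the second summary 4393. The 2 lines are separate transfected populations with 1 array per time, so the mutation, the history of each population and its handling cannot be separated here.

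**Figure D1:**
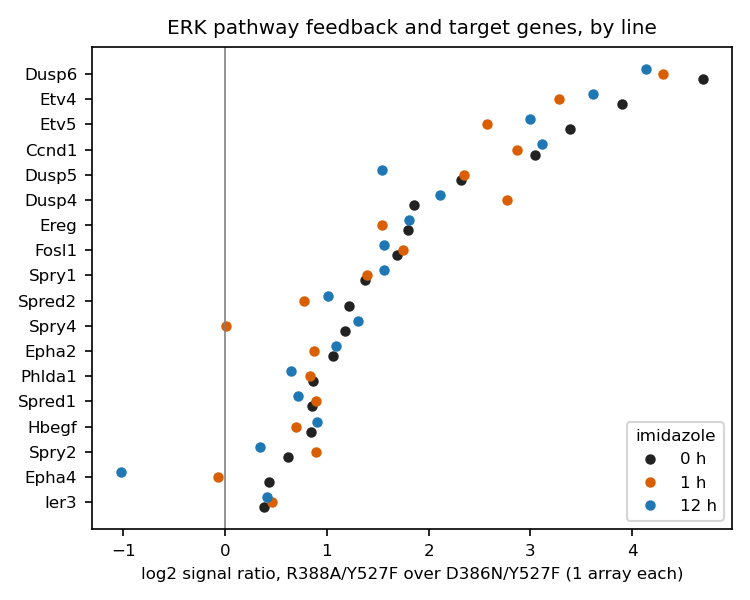
Log2 ratio of signals, R388A/Y527F over D386N/Y527F (horizontal axis), for 18 genes of the ERK feedback and target list, with 1 point per time after imidazole. Dusp6 lies at 4.70, 4.30 and 4.14 at 0, 1 and 12 h, and Epha4 lies below 0 at 1 h (-0.07) and 12 h (-1.03).

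The comparison of 1 h with 0 h in the R388A/Y527F line asks for early responses to a restored kinase. Cytoskeletal genes were slightly lower and immediate early genes did not stand apart. The list of actin cytoskeleton, SRF and YAP targets had a median of -0.09 at the 0.58th percentile (-0.18 and 0.01 in the second summary), with Srf, the serum response factor gene, at -0.52 and Ccn1 at -0.45. Immediate early genes had a median of 0.01 at the 83.6th percentile (28.3 in the second summary), ERK targets -0.11 at the 16.7th and STAT3 targets -0.12 at the 11.9th. Sterol synthesis genes had a median of 0.14 at the 99.7th percentile (0.05 and 99.8), with Hmgcs1 at 0.41 and Insig1 at 0.37. The largest change in that list went the other way, Srebf2 at -0.73 (-0.52), and Dhcr7 also fell, at -0.33 (-0.24). Metal response genes had a median of 0.25 at the 98.3rd percentile (97.1 in the second summary), with the metallothionein gene Mt1 at 0.87 (0.43), from a 0 h signal of 8.5 below the floor, Mt2 at 0.42 (0.33) and the zinc exporter gene Slc30a1 the other way at -0.53 (-0.52). NRF2 targets had a median of 0.12 at the 98.7th percentile, and -0.09 in the second summary. Protease and transformation markers stood at the 1.00th percentile and at the 31.4th in the second summary. The Src family list had a median of -0.39 at the 1.49th percentile, without standing apart in the second summary (3.70), with Src at -1.71 (-0.34) and Csk, the kinase that inhibits Src, at -0.51 (-0.55). Actin, NRF2 and protease lists no longer stood apart with the mean of all probe sets, NRF2, protease and metal response lists under quantile normalization, and the Src family list with a pseudocount or the higher floor, the last also for the protease list.

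In R388A/Y527F at 1 h 133 genes were 2-fold higher and 134 lower, and the second summary called 1 higher and 10 lower. The 2 genes that passed in both were Malat1, a nuclear long noncoding RNA, at 1.52 (1.63 in the second summary), and the semaphorin gene Sema3f at -1.38 (-1.14). The Malat1 signal was 202.9 at 0 h and 582.4 at 1 h, and lay between 539.1 and 599.4 in the D386N/Y527F line. The 7 Malat1 probe sets were all higher at 1 h in R388A/Y527F, by 0.179 to 1.603 (0.167 to 1.919 in the second summary). The genes named by the rule were Gdnf, Kcna7, Pnmt, Upk2, Mroh2a, Jph1, Dus2 and Ninj2 on the higher side, from 1.53 to 1.92, and Zap70, Acsf2, Lfng, Myoz1, Acta1, Trpc1, Svep1 and Adam4 on the lower side, from -2.91 to -1.81. Of these 16 genes, 10 had an array at the floor and 0 were 2-fold different in the second summary.

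After 12 h in the R388A/Y527F line, genes of lysosomes and of sterol synthesis were higher and genes of mitosis lower. Of 18 lysosome and autophagy genes 17 were higher, with a median of 0.41 (0.41 in the second summary), above every one of 10000 random lists. They included Rragd, a GTPase gene of lysosomal nutrient signalling, at 1.00 (1.01), the sialidase gene Neu1 at 0.63 (0.92) and the proton pump subunit gene Atp6v0d1 at 0.60 (0.71). Of 19 sterol synthesis genes 18 were higher, with a median of 0.48 (0.49), also above every random list, among them Msmo1 at 1.12 (0.74), Fdps at 0.67 (0.66), Hmgcs1 at 0.63 (0.58) and Fdft1 at 0.62 (0.57). Of 22 G2/M genes 20 were lower, with a median of -0.13 (-0.24), below every random list, with Cenpe at -0.40, Aurkb at -0.37 and Mki67 at -0.30. NRF2 targets had a median of -0.11 at the 2.46th percentile, with glutathione reductase, Gsr, at -0.57. Immediate early genes had a median of -0.13 at the 0.87th percentile (17.7 in the second summary), with Jun at -0.60 and Klf2 at -0.58. Lipogenesis and LXR targets stood at the 97.8th percentile and at the 64.6th in the second summary. ERK targets stood at the 31.3rd percentile with -0.07, STAT3 targets at the 82.8th and quiescence genes at the 19.5th. Lipogenesis targets no longer stood apart with the mean of all probe sets, under quantile normalization or with the higher floor, NRF2 targets under quantile normalization, and immediate early genes with the higher floor or the 1 h array in place of the 0 h array.

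In this 12 h comparison 115 genes were 2-fold higher and 140 lower (12 and 8 in the second summary). The 5 genes that passed in both were Rab20, a small GTPase gene (1.31), Uap1l1 (1.12), Tm7sf2, a sterol reductase gene (1.03), Rragd (1.00) and, on the lower side, the regulator of G protein signalling Rgs4 (-1.02). The genes named by the rule were Kcna7, G6pc3, Il18bp, Zfp433, Ccdc166, Herc6, B3galt5 and Omp, at most 2.64, and Acsf2, Prdm11, Col9a1, Dcc, Cstdc2, Fam131a, Art1 and Il1f10, from -2.14 to -1.68. Of these 16 genes, 11 had an array at the floor and 0 were 2-fold different in the second summary.

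The D386N/Y527F line at 1 h served as the control for imidazole itself. Sterol synthesis genes had a median of 0.05 at the 98.9th percentile (0.03 and 99.8), with Hsd17b7 at 0.35 (0.46) and Ebp the other way at -0.26 (-0.23). Heat shock genes had a median of -0.12 at the 1.64th percentile (0.72 in the second summary), with 12 of 13 lower, among them Hspb8 at -0.39 and the co-chaperone gene Dnajb1 at -0.21. G2/M genes stood at the 2.40th percentile with -0.09 (2.97) and p53 targets at the 1.94th with -0.13 (31.2). The 3 adipocyte markers stood at the 0.74th percentile (0.83), with a median of -0.63 that is again Pparg on the 0 h array over the floor. Immediate early genes had a median of 0.04 at the 88.2nd percentile. G2/M, heat shock and p53 lists no longer stood apart with the mean of all probe sets, G2/M genes under quantile normalization, p53 and adipocyte lists with a pseudocount and p53 targets with the higher floor. By the 2-fold rule 226 genes were higher and 70 lower, and the second summary called 2 and 8. Slc30a1, a zinc exporter gene (-1.49), the skeletal actin gene Acta1 (-1.44) and Trmt5 (-1.01) passed in both. The genes named by the rule were Cstdc2, Ccr2, Dio3os, Tlr9, Snx29, Pnmal1, Shq1 and Rtbdn, from 1.55 to 1.89, and Atxn7l2, Kcna7, Cdc42bpb, Rnf113a1, Tnni3, Map3k1, Rasl10a and Meak7, from -2.31 to -1.64. Of these 16, 11 had an array at the floor and 0 were 2-fold different in the second summary. Of the called genes 76.4% were higher, and 53.5% under quantile normalization.

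After 12 h in the D386N/Y527F line, lysosomal and sterol synthesis genes were again higher and mitotic genes lower. Of 18 lysosome and autophagy genes 16 were higher, with a median of 0.53 (0.46 in the second summary), above every one of 10000 random lists, led by Rragd at 1.83 (2.23), the hexosaminidase gene Hexa at 0.82 (0.87) and Neu1 at 0.75 (0.73). Of 19 sterol synthesis genes 17 were higher, with a median of 0.24 (0.28), also above every random list, with Lss at 0.44 and Msmo1 at 0.40. All 22 G2/M genes were lower, with a median of -0.26 (-0.28), below every random list, with Aurkb at -0.86 and Bub1 at -0.53. The unfolded protein and amino acid response list had 18 of 22 genes lower, a median of -0.20 and the 0.04th percentile (0.56), with Mthfd2 at -0.90 (-1.03), the asparagine synthetase gene Asns at -0.67 (-0.85) and Psat1, of serine synthesis, at -0.62 (-0.69). Fibroblast matrix genes had a median of 0.14 at the 99.7th percentile (0.20, above every random list), with Dcn at 0.65 (0.75), the fibronectin gene Fn1 at 0.65 (0.66) and Thbs2 at 0.59 (0.62). NRF2 targets stood at the 0.23rd percentile with -0.20, with Srxn1 at -0.55. Circadian clock genes stood at the 99.7th percentile with 0.36 and at the 58.5th in the second summary. The 3 adipocyte markers stood at the 0.84th percentile (0.63) through the same Pparg value of -0.63, with Cebpa at 0.72 (-0.44). NRF2, circadian and adipocyte lists no longer stood apart with the mean of all probe sets, adipocyte markers with a pseudocount and circadian genes with the 1 h array in place of the 0 h array (53.7th percentile).

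In the D386N/Y527F line at 12 h 224 genes were 2-fold higher and 80 lower (26 and 17 in the second summary), and 14 and 4 passed in both. These included the lipid droplet gene Plin4 (2.38), Rragd (1.83), Itm2a (1.40), Uap1l1 (1.24), the laminin gene Lama4 (1.23), the lysosomal peptidase gene Dpp7 (1.15) and the fibrillin gene Fbn2 (1.11), and on the lower side Stra6 (-1.28), Prkd1 (-1.24), Cth, of cysteine synthesis (-1.20), and the histone gene H1f2 (-1.02). The genes named by the rule were Plin4, Rundc3a, Rragd, Snx29, Svep1, Zfp57, Ccdc14 and Rph3a, from 1.68 to 2.38, and Kcna7, Fancm, Ceacam1, Tmem141, Mroh2a, Arc, Hrh3 and Tnfrsf13c, from -2.22 to -1.47. Of these 16, 10 had an array at the floor, and Plin4 and Rragd were 2-fold different in the second summary. Of the called genes 73.7% were higher, and 51.6% under quantile normalization.

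**Figure D2:**
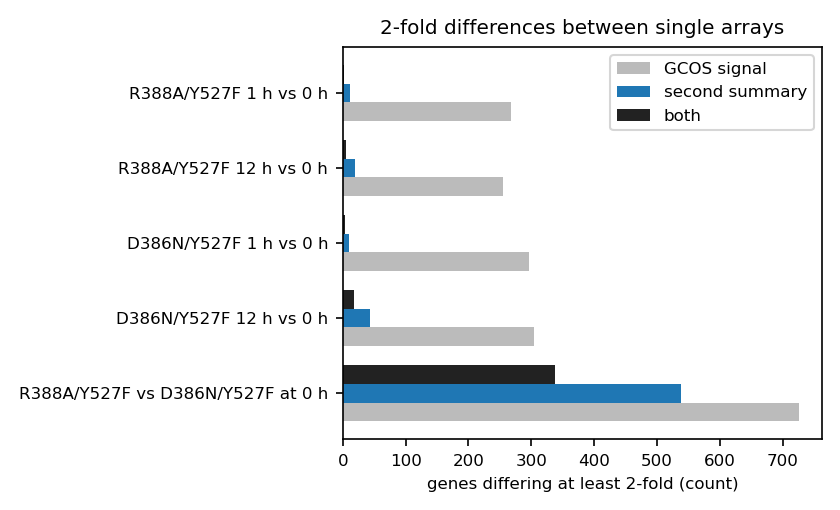
Number of genes with a difference of at least 2-fold between single arrays (horizontal axis) for 5 comparisons, in the GCOS signal, in the second summary and in both. The GCOS signal gives 255 to 304 genes within a line and the second summary 10 to 43, while the 2 lines at 0 h differ by 726 and 538 genes.

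Changes common to both lines were tested with limma, with the lines as the replicates of a time. At 12 h Uap1l1 rose by 1.18 (SE 0.11, adjusted p = 0.0202) and Dpp7 by 1.07 (SE 0.10, adjusted p = 0.0202), each higher in both lines. These 2 were the only calls over all genes in the limma fit, and 1135 genes had an unadjusted p under 0.05. Both calls ended in limma with the mean of all probe sets, with no filter and without a trend, and that of Dpp7 in the second summary (adjusted p = 0.0873). Among 18 lysosome and autophagy genes 12 rose when adjusted over the list alone and 0 over all genes, and 17 had a positive change. They included Hexa (0.70, SE 0.10), Neu1 (0.69, SE 0.16), Atp6v0d1 (0.60, SE 0.09), the calcium channel gene Mcoln1 (0.58), the folliculin gene Flcn (0.54) and Lamp1 (0.45). Among 19 sterol synthesis genes all had a positive change, and 13 rose adjusted over the list alone and 0 over all genes, among them Msmo1 (0.76, SE 0.16), Fdps (0.48), Sc5d (0.47) and Cyp51 (0.41). Of 22 G2/M genes 0 changed, over all genes or adjusted over the list alone, in the limma fit of the GCOS signal, and 16 fell adjusted over the list alone in that of the second summary. Of 14 NRF2 targets 3 fell adjusted over the list alone and 0 over all genes, Srxn1 (-0.53), Gsr (-0.47) and Pgd (-0.31). At 1 h limma called 0 genes, and 530 had an unadjusted p under 0.05. Adjusted over their list alone, Gclm (0.59) and the clock gene Bhlhe40 (0.72) rose and Acta1 (-1.68) fell at 1 h.

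Across genes above the floor on all arrays, the changes of the 2 lines correlated at 12 h with r = 0.15 (0.39 in the second summary) and at 1 h with r = -0.03 (0.01). The lines share no array, and genes are not independent replicates. In the GCOS signal 12 genes were 2-fold higher in both lines at 12 h, 4 lower in both and 18 opposite, and at 1 h these numbers were 8, 6 and 15. The second summary had 5 genes higher in both lines at 12 h, Dpp7, Renbp, Rragd, Tm7sf2 and Uap1l1, with 0 lower in both and 0 opposite.

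**Figure D3:**
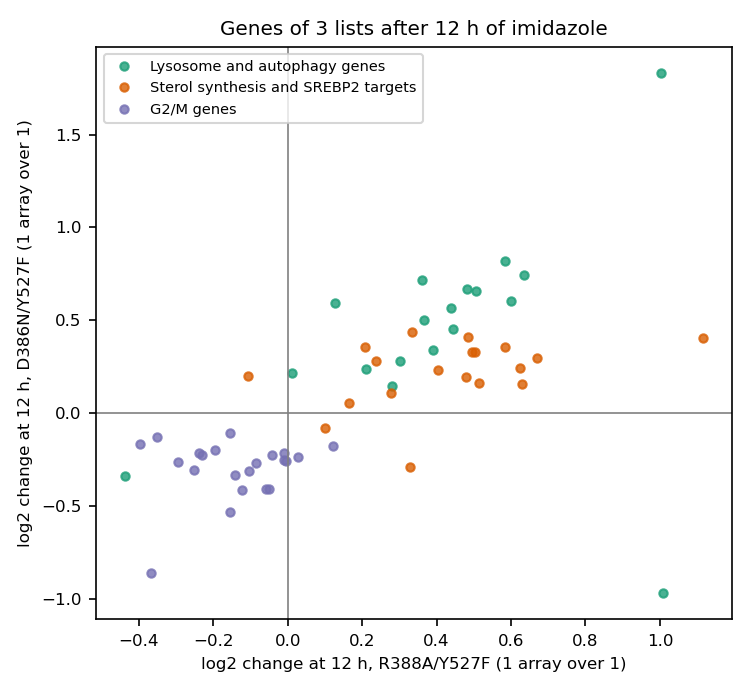
Log2 change after 12 h of imidazole in R388A/Y527F (horizontal axis) and D386N/Y527F (vertical axis), 1 array over 1 in each, for genes of 3 lists. In both lines 16 of 18 lysosome and autophagy genes and 16 of 19 sterol synthesis genes lie above 0, and 20 of 22 G2/M genes lie below 0.

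The question of the series, which changes depend on the restored kinase, is addressed by the difference of changes between the lines. The lines are separate populations, so a restored kinase and another difference in how each responds to imidazole or time cannot be told apart. At 12 h the change of the unfolded protein and amino acid response genes was higher in R388A/Y527F than in D386N/Y527F, where 18 of 22 were lower than at 0 h. The difference of changes was positive for 21 of 22, with a median difference of 0.27 (0.25 in the second summary) at the 99.99th percentile, among them Trib3 at 1.61 (0.51), Mthfd2 at 0.86 (1.00) and Chac1 at 0.68 (1.07). Neither this list nor the fibroblast matrix list stood apart at 12 h in R388A/Y527F itself, while both did in D386N/Y527F. Mthfd2 signals went from 430.4 to 419.1 in R388A/Y527F and from 497.4 to 266.4 in D386N/Y527F. In the GCOS signal Trib3 moved in both lines, from 65.3 to 111.1 and from 61.1 to 34.1. In the second summary its log2 change was 0.54 in R388A/Y527F and 0.03 in D386N/Y527F, so the fall was absent there. Sterol synthesis genes had a median difference of 0.17 at the 98.5th percentile (0.21 and 99.96), with Msmo1 at 0.71 (0.22) and Hmgcs1 at 0.47 (0.34). This list had a low median in R388A/Y527F at 0 h, as had G2/M genes, and the difference of changes subtracts that array. Hmgcs1 signals in R388A/Y527F and D386N/Y527F were 2875.8 and 4184.9 at 0 h and 4449.4 and 4662.8 at 12 h. Those of Msmo1 were 1228.3 and 1427.4, then 2662.5 and 1889.8. With the 1 h arrays as baseline, the sterol medians at 12 h were 0.44 and 0.18. With 1 array per time, a low 0 h value and a larger rise cannot be told apart. Fibroblast matrix genes had a median difference of -0.16 at the 0.05th percentile (-0.21, below every random list), with Dcn at -0.42 (-0.53) and Postn at -0.40 (-0.21). Lysosome and autophagy genes had a median difference of -0.12 at the 1.00th percentile (-0.09 and 0.35), with Rragd at -0.83 (-1.21) and Npc1 at -0.47 (-0.35). G2/M genes stood at the 99.7th percentile with 0.20 and at the 82.8th in the second summary. ERK targets stood at the 22.6th percentile with -0.13 and immediate early genes at the 82.3rd with 0.02. Sterol synthesis, lysosome and G2/M lists no longer stood apart with the mean of all probe sets, and G2/M genes not under quantile normalization.

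At 1 h the difference of changes set apart actin, SRF and YAP targets (median -0.11, 1.6th percentile, and -0.15 in the second summary), with Srf at -0.71 (-0.32). Metal response genes had a median difference of 0.36 at the 99.2nd percentile (0.20 and 97.7), with Mt1 at 0.48 (0.40) and Slc30a1 at 0.97 (0.50), which was lower at 1 h in both lines, by less in R388A/Y527F (-0.53 and -1.49). The Src family list had -0.66 at the 0.72nd percentile (1.78), with Src at -2.03 (-0.48) and Csk at -0.66 (-0.48), and quiescence genes 0.25 at the 99.8th (95.8). Immediate early genes had a median difference of 0.05 at the 88.8th percentile and ERK targets -0.16 at the 16.2nd. Actin and quiescence lists no longer stood apart with the mean of all probe sets, and metal response genes under quantile normalization or with the higher floor.

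By the 2-fold rule the change differed for 79 genes in the higher and 95 in the lower direction at 1 h, and for 66 and 96 at 12 h. The second summary gave 1 and 7 at 1 h and 5 and 2 at 12 h. Malat1 at 1 h, at 1.53 (1.59), was the only gene in both, and at 12 h there were 0. Scaling to the median of probe sets above the floor moved the share of higher genes at 1 h from 45.4% to 57.0%, and quantile normalization moved that at 12 h from 40.7% to 52.9%. The genes named by the rule at 1 h were Kcna7, Gdnf, Pnmt, Mmp23, Mroh2a, Epm2a, Slc39a5 and Ninj2, from 1.76 to 4.12, and Zap70, Snx29, Myoz1, Svep1, Myl3, Wnt6, Plin4 and Ptprcap, from -3.82 to -2.44. At 12 h they were Kcna7, B3galt5, Syt8, Omp, Herc6, Gpnmb, Slc22a12 and Zfp433, from 1.89 to 4.86, and Svep1, Dcc, Cstdc2, Gpr20, Prdm11, Gapdhs, Pcsk6 and Acsf2, from -3.34 to -2.48. Of these genes 0 differed 2-fold in the second summary. Some could not, since their difference there was exactly 0, as signals at that floor give, among them Snx29 and Wnt6 at 1 h and B3galt5, Syt8 and Gapdhs at 12 h. The limma interaction of line and treatment called 0 genes, and 462 had an unadjusted p under 0.05. It takes the 1 h and 12 h arrays of a line as 2 treated samples. A difference present at only 1 of these times therefore adds to its residual spread and is easily missed. Of the 30 lists, 0 had a member past the interaction's threshold in the GCOS signal, over all genes or adjusted over the list alone, and 1 list had 1 such member in the second summary.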

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

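The tests of quiescence genes after 12 h, of ERK genes under quantile normalization and of other splits of the arrays were chosen after the result was seen, as were the spread used to read the test on probe sets without a gene symbol and the choice to look at other long noncoding RNAs, for which no bound was set.

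Some genes differed 2-fold in opposite directions in the 2 lines, which drew attention to them. The difference at each hour was not tested, since each line had 1 array per time. The limma interaction of line and treatment, over both hours together, called 0 genes, with 462 at an unadjusted p under 0.05. The values are log2 changes in R388A/Y527F minus those in D386N/Y527F. At 1 h they were positive for Kcna7 (4.12), Cryl1 (2.92) and Hspbap1 (2.61) and negative for Snx29 (-3.15), Myl3 (-2.80), Spata3 (-2.78), Wnt6 (-2.66), Fjx1 (-2.54), Plin4 (-2.52), Mrgpra3 (-2.40), Ltf (-2.31), Igsf23 (-2.29), Smoc1 (-2.25), Krt77 (-2.17) and Slc16a9 (-2.10). At 12 h they were positive for Kcna7 (4.86), Pnmt (3.29), B3galt5 (3.21), Rims4 (2.86), Syt8 (2.53), 1600014C23Rik (2.48) and Cep126 (2.12) and negative for Svep1 (-3.34), Utf1 (-2.87), Dcc (-2.78), Dnajc22 (-2.77), Gpr20 (-2.62), Gapdhs (-2.55), Pcsk6 (-2.53), Kcna2 (-2.45), 9630015K15Rik (-2.18), 4930545L23Rik (-2.14) and Ctcflos (-2.12). Of these 15 genes at 1 h and 18 at 12 h, 0 had a 2-fold difference in the second summary, where the largest absolute differences were 0.61 and 0.66. Many had a difference of exactly 0 there, as signals at that summary's floor give, and so could not show one. At 1 h these were Krt77, Ltf, Mrgpra3, Slc16a9, Snx29, Spata3 and Wnt6. At 12 h they included B3galt5, Syt8, Utf1, Kcna2, Gapdhs and Dnajc22.

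Lysosome and sterol synthesis genes were higher at 12 h in both lines. Array scaling was argued against, since the lowest of the 4 list medians was still 0.28 under quantile normalization. Lysosomal genes outside the fixed list were higher as a class too, at the 100th percentile in both lines (32 of 39 genes in R388A/Y527F and 34 of 38 in D386N/Y527F). The quiescence list lay at the 19.5th percentile in the lower of the 2 lines, which speaks only to a general quiescence programme. Because no 12 h array without imidazole was among the 6, imidazole and 12 more hours without serum cannot be told apart, and either could account for the pattern.

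ERK target genes were higher in R388A/Y527F at 0 h. Scaling was argued against, since the list's median was 1.27 under quantile normalization against 1.29 without it. No imidazole had been added at 0 h, so activity restored by imidazole is no account of this difference. An effect of the 2 Src mutants without imidazole, and a difference between the 2 transfected populations unrelated to Src, both stay open, and neither was tested.

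Malat1 was higher at 1 h than at 0 h in R388A/Y527F. The 0 h signal of that line was 0.362 of the mean of the 3 D386N/Y527F arrays, as a low value on that array would give, but the line's 12 h signal of 381.5 also lay below the 539.1 to 599.4 of D386N/Y527F. For more nuclear or unspliced RNA on the 1 h array, probe sets without a gene symbol moved by 0.0442 more than those with 1 symbol (0.0526 in D386N/Y527F), under the bound of 0.05 by less than the spread between arrays, 0.0133. A list of 9 other long noncoding RNAs stood at the 99.4th percentile in R388A/Y527F (99.8 in the second summary) and the 97.6th in D386N/Y527F (93.7), but several lay near the floor and 3 were snoRNA host genes whose RNA leaves the nucleus, so it decides nothing and the explanation stays open. With 1 array per time, a low 0 h value of the cells and of the array cannot be told apart, and either could be the source.

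The limma fit called 2881 genes between the lines, and the highest of the 9 other splits of the 6 arrays into 3 and 3 called 0. Only 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. Every other split puts arrays of both lines in each group, so a difference between the lines adds to its residual spread. Any strong line difference would give few calls there, so the 0 says nothing about its source. The test cannot separate the mutation from the history or handling of each population.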

How the results depend on the processing

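The second summary, the floor at the 60th percentile and the 1 h array as baseline were tests chosen after the result was seen. Total counts of 2-fold genes kept within 1.5 times their value under quantile normalization and median scaling, but in D386N/Y527F the higher and lower counts went from 226 and 70 to 147 and 128 at 1 h, and from 224 and 80 to 145 and 136 at 12 h, under quantile normalization. Of the 43 list medians that stood apart, all 43 still did under median scaling and 32 under quantile normalization, where the other 11 kept their direction. With the mean of all probe sets only 25 did, 17 no longer stood apart and 1 reversed. With the higher floor 31 did and 8 did not, with a pseudocount 38 and 5, and in the second summary 28 did, 11 did not and 3 reversed, and 4 and 1 of the 43 had too few members for a median with the higher floor and in the second summary. Under the floor at the 60th percentile the counts were 22 and 26 in R388A/Y527F at 1 h and 12 h, 13 and 39 in D386N/Y527F, 318 between the lines at 0 h and 15 and 10 for the difference of changes. The second summary gave 11, 20, 10 and 43 within lines and 8 and 7 for the difference of changes. With the mean of all probe sets they were 141, 135, 160, 167, 467, 87 and 86, and with a pseudocount 186 and 189 in D386N/Y527F and 115 for the difference at 1 h. Of the 112 genes named by size, 33 stayed 2-fold in direction with the higher floor and 18 in the second summary. Raising the floor, which acts on low signals, lowered each of these counts.

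The limma line count was 4393 in the second summary, 1099 without a trend, and 1708, 642 and 500 without the 0 h, 1 h and 12 h arrays, and the 16 genes named from it stayed past the threshold in each of these. The common 12 h count was 4 under quantile normalization, 15 with a pseudocount, 21 with the higher floor and 1 in the second summary, where Dpp7 had an adjusted p of 0.0873. It was 0 in limma with the mean of probe sets (1099 at an unadjusted p under 0.05), with no filter (1119) and without a trend (956). The common 1 h count and the interaction count were 0 in limma in every setting run, with 341 to 639 and 285 to 825 genes at an unadjusted p under 0.05.

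Directions reversed in the second summary for the NRF2 list in R388A/Y527F at 1 h (-0.094), for circadian genes at 0 h (-0.055) and in D386N/Y527F at 12 h (-0.032), with the mean of probe sets for p53 targets in D386N/Y527F at 1 h (0.012), and with the 1 h baseline for lipogenesis genes in R388A/Y527F at 12 h (-0.041). With that baseline immediate early genes in R388A/Y527F (6.47th percentile) and circadian genes in D386N/Y527F (53.7) also no longer stood apart. Genes that reversed in the second summary were, in R388A/Y527F at 1 h, Kcna7 (-0.028), Mroh2a (-0.075), Myoz1 (0.01), Trpc1 (0.105) and Adam4 (0.017), and at 12 h Kcna7 (-0.111), Ccdc166 (-0.046), Acsf2 (0.106), Col9a1 (0.024) and Dcc (0.057). In D386N/Y527F they were Shq1 (-0.062) and Kcna7 (0.059) at 1 h and Ccdc14 (-0.165) and Mroh2a (0.014) at 12 h. The difference of changes reversed for Kcna7 (-0.087 and -0.104) and Mroh2a (-0.074 at 1 h). The causes were not tested. A floor from Absent calls was not run, since no calls were given. Series values in place of the table were not run, since 0 values differ.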

Other observations

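The test with the 1 h array in place of the 0 h array was chosen after the result was seen, and the class of other lysosomal genes was added to the fixed lists after the list's values were seen.

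Genes of lysosomal enzymes and proton pump subunits outside the fixed list, grouped by the start of their symbols, had a median log2 change at 12 h of 0.29 in R388A/Y527F and 0.28 in D386N/Y527F (0.24 and 0.25 in the second summary). At 1 h this group stood at the 81.4th and 92.5th percentile, without standing apart. With the 1 h array in place of the 0 h array, the fixed lysosome list at 12 h had a median of 0.32 in R388A/Y527F and 0.47 in D386N/Y527F, and the sterol synthesis list 0.44 and 0.18. Tcn2, which encodes the vitamin B12 carrier transcobalamin, had signals of 87.2 at 0 h and 193.2 at 12 h in R388A/Y527F and of 137.0 and 337.4 in D386N/Y527F, and it was under 2-fold in the second summary (0.96 and 0.94).

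Of 203 pairs of list and comparison, 43 stood apart, 19 on the high and 24 on the low side, and the 7 comparisons share arrays, so these pairs are not separate results. Of these, 28 also stood apart on the same side in the second summary.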
